A study of Homo sapiens with 22 samples.

How the data were processed

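RNA was measured in differentiated LUHMES cells, either wild type or overexpressing alpha-synuclein, with or without 6-OHDA, and in 6-OHDA-treated alpha-synuclein cells with quercetin or rutin. Per the labels' protocols, polyadenylated RNA was extracted with an InnuPREP kit and made into libraries with an MGIEasy kit. The values analysed were estimated counts per Ensembl gene, as deposited by the authors, in whole numbers and not normalised. Trimmomatic 0.38, kallisto 0.46.2 and the human builds GRCh38 and hg38 are named per the submitters' processing notes, without their order or role. How transcript estimates were summed to genes, the annotation release and any filter on reads are not given in the sources used here.

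Kallisto divides reads that match several transcripts among them, so levels of near-identical genes are uncertain. This holds for keratins, for ribosomal protein genes and their pseudogenes, and for mitochondrial genes with nuclear copies. MT-ND4L also overlaps MT-ND4, so their counts cannot be fully separated. Whether strand was used is not given in the sources used here, so antisense partners are uncertain as well.

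The table held 34679 genes, of which 29867 had a count. All 22 columns were matched to samples by name, and each sample's group and replicate number came from its title. Positions were taken from GENCODE 29 on GRCh38, where 34658 IDs (99.9%) matched without their version and 24717 (71.3%) with it. Rows of pseudogenes took 1.76% of counts, and 19 symbols were shared by several IDs. Replicate pairs within a group differed by more than sampling noise, with a chi-square per degree of freedom of 2.87 to 26.2, so no library was counted as a copy of another. Replicate correlations of log2 CPM were 0.931 to 0.988. The labels name 4 libraries in each group without a compound and 3 in each compound group, but nothing says they came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

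Counts were rounded and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, which left 16601 genes (14717 protein coding, 1861 pseudogenes) and set aside 0.174% of counts. Libraries were scaled by TMM, and glmQLFit and glmQLFTest were run on group means of all 22 libraries, so that the 6 groups shared 1 estimate of spread. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and SEs were derived from the fold change and its F statistic. Levels are given as CPM with TMM-scaled library sizes. Principal components were taken from log2 CPM with a prior count of 2. Totals ran from 1.87 M to 20.67 M counts (M, mega), and a floor of 3 counts corresponded to 0.168 to 1.49 CPM on that scale. Floors and intervals cover counting error or the spread between these libraries, and molecular identifiers are not named in the sources used here.

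The 9 comparisons were 6-OHDA in each genotype, alpha-synuclein without and with 6-OHDA, treated alpha-synuclein against untreated wild-type cells (the combined model), the interaction of genotype and 6-OHDA, quercetin, rutin, and quercetin against rutin. Library names place 12 libraries on lane 1 and 10 on lane 2. Lane followed the groups in 6-OHDA in alpha-synuclein cells, alpha-synuclein in 6-OHDA cells, the combined model and the interaction, where no lane term could be fitted and lane and group cannot be told apart. Of the untreated alpha-synuclein libraries 2 carry 4 barcode numbers in their names, unlike the other 20.

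The tests, comparisons, gene lists, rule for named genes and most alternatives were fixed before the data were examined. The rule took fixed genes, among them CEBPB, AKR1C3 and TH, in every comparison, the 10 largest changes each way among called genes with a mean of 5 CPM or more in a group and no overlap between libraries (not required for the interaction), and 4 members of each list with the smallest adjusted p. The text names part of the genes this rule gives, and that part was chosen after their values were seen. Results of some genes are not reported here. Chosen outside the rule after their values were seen were KRT19, KRT40 and KRT33B (alpha-synuclein in 6-OHDA cells) and SNCG (quercetin and rutin). The same holds for HERPUD1, PDIA6, DNAJB11, HSP90B1, NGFR, SNED1, LCNL1, RELB, SLC7A11 and HMOX1 in rutin and in quercetin against rutin, taken over from other comparisons.

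The 32 gene lists held 507 entries, of which 485 were in the table and 429 were tested, 15 genes were matched by ID under an older symbol, and 21 genes were not analysed here. Each list was tested with camera from limma 3.58.1 at a preset correlation of 0.01, with adjustment over the lists of a comparison, and again with an estimated correlation and with fry. The lists covered NRF2 targets, ATF4 and the integrated stress response, ER chaperones, heat shock proteins, p53 targets, immediate-early genes, proteasome, autophagy, C/EBP family, aryl hydrocarbon receptor targets, aldo-keto reductases, metallothioneins, iron handling, hypoxia, cholesterol synthesis, mitochondrial mRNAs, nuclear complex I and ribosomal proteins. They also covered pan-neuronal, dopaminergic, other neurotransmitter, axon guidance, progenitor, astrocyte, oligodendrocyte, microglia and fibroblast genes, and cell cycle, histone, Parkinson disease, NF-kappaB and interferon genes.

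Alternatives fixed beforehand were DESeq2-style size factors, DESeq2 1.42.0, no filter, a filter of 1 CPM in 3 libraries, a fit of the compared groups alone, the replicate number as a block, each library left out, and leaving out the 2 libraries with several barcode numbers. Added after seeing the data were thinning every library to the shallowest total, removing each library's trend with GC content and transcript length by offsets, and lists without treated alpha-synuclein replicate 4. GC content was known for 16573 tested genes (99.8%). Removing a trend may also remove effects that are linked to GC content.

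The scripts were tested on simulated counts with known changes. At a true 2-fold change, 55.4% of changed genes were recovered for 6-OHDA in wild-type cells, 53.8% for quercetin and 65.7% for rutin. A further simulation, of alpha-synuclein in 6-OHDA cells, pooled true changes of 1.5, 2 and 4-fold. Without GC trends, edgeR recovered 62.2% of these genes with 3 false calls and DESeq2 66.3% with 13. With the measured GC trends, edgeR without correction made 1498 false calls among 1629, and with correction 7 among 121 while recovering 59.4%. The simulated trends were those that the correction itself fits, so its success there was built in. The simulation therefore cannot show which calls in the real data are false. Overlaps of comparisons that share control libraries were set beside 20 simulations without effects and beside splits of those libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.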

Results

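LUHMES cells are a conditionally immortalised human mesencephalic line that differentiates into post-mitotic neurons with dopaminergic features. Polyadenylated RNA was sequenced from wild-type LUHMES cells and from cells overexpressing alpha-synuclein, a protein that accumulates in Lewy bodies. Both genotypes were left untreated or received 6-hydroxydopamine (6-OHDA), a dopamine analogue whose oxidation produces reactive oxygen species. According to the design text, 6-OHDA served to build cell models of Parkinson disease. Treated alpha-synuclein cells also received quercetin, a flavonol tied in that text to CEBPB, or rutin, a glycoside of quercetin, tied to a name read here as AKR1C3. The 22 libraries fell into 6 groups, with 4 libraries in each group without a compound and 3 in each compound group.

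Estimated counts per library summed to 6.11 to 10.61 M (mega) in untreated wild-type cells and 8.11 to 20.67 M in untreated alpha-synuclein cells. After 6-OHDA the totals were 12.64, 3.12, 2.04 and 1.87 M in wild-type replicates 1 to 4, and 5.41, 2.52, 3.93 and 18.61 M in alpha-synuclein replicates 1 to 4. Quercetin libraries held 6.39, 13.71 and 12.79 M counts, and rutin libraries 7.48, 8.54 and 2.59 M. A level of 3 counts corresponded to 0.168 to 1.49 CPM (counts scaled to library size), so genes below that were near the detection limit in the shallowest libraries. Of 34679 genes, 16601 were tested.

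The largest component of variation separated cells with and without 6-OHDA. On the first principal component, which held 40.8% of the variance, untreated libraries scored -76.4 to -53.5. All treated libraries but alpha-synuclein replicate 4 scored 35.8 to 45.3, and that library scored -1.47. The second component, with 10.8% of the variance, had a mean of -46.3 in treated wild-type cells and 20.6 in treated alpha-synuclein cells. Sequencing lane 1 carried the 12 libraries of untreated cells and of treated wild-type cells, and lane 2 the remaining 10.

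**Figure D1:**
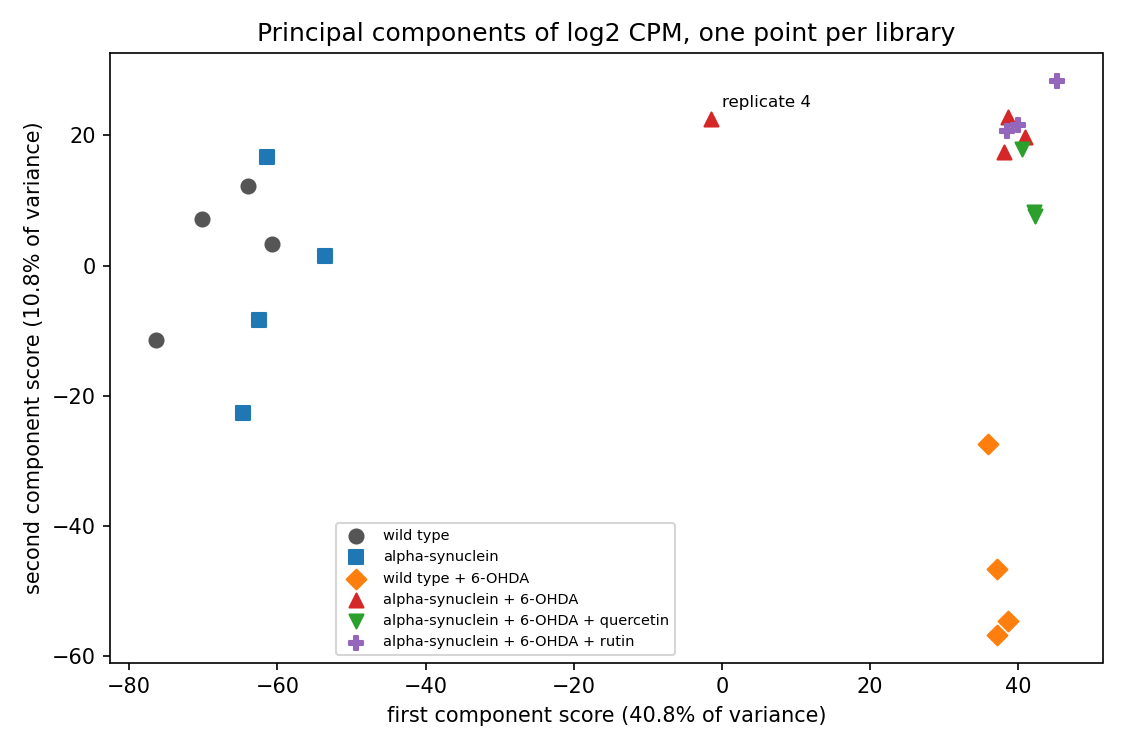
Scores of the 22 libraries on the first and second principal components (axes, with percent of variance) of log2 CPM values, 1 point per library, coloured by group. Untreated libraries lie at -76.4 to -53.5 on the first component, and replicate 4 of 6-OHDA-treated alpha-synuclein cells lies alone at -1.47.

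The effect of 6-OHDA was measured first in wild-type cells, within lane 1. All fold changes below are on the log2 scale ± SE, levels are mean CPM ± SD over the libraries of a group (n = 4 unless given), and adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The transcription factor gene CEBPB (ENSG00000172216.5, plus strand of chromosome 20, 50190734 to 50192689 in GRCh38) rose from 2.86 CPM ± 0.659 to 108 CPM ± 16.1, a log2 change of 5.27 ± 0.18 (adjusted p = 2.32e-15). Oxidative stress genes were among the strongest responders, with HMOX1, which encodes the haem-degrading enzyme haem oxygenase 1, at 6.92 ± 0.50. TH, the rate-limiting enzyme of dopamine synthesis (ENSG00000180176.14, minus strand of chromosome 11, 2163929 to 2171877), dropped from 374 CPM ± 20.6 to 126 CPM ± 7.72 (-1.57, adjusted p = 1.03e-08). AKR1C3, an aldo-keto reductase (ENSG00000196139.14, plus strand of chromosome 10, 5035354 to 5107686), stayed near the detection limit, at 0.754 CPM ± 0.512 and 0.956 CPM ± 0.356, with a change of 0.12 ± 0.58 (adjusted p = 0.883).

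Stress pathways rose together in these wild-type cells. Among NRF2 targets, the antioxidant genes controlled by that factor, 17 of 18 tested rose and 0 fell, including the quinone reductase NQO1 (3.94 ± 0.18), sulfiredoxin SRXN1 (2.56 ± 0.11), the glutathione synthesis subunit GCLM (2.93 ± 0.15) and the iron store FTH1 (1.93 ± 0.10). The ATF4 and integrated stress response list had 17 of 19 rising, among them DDIT3 (CHOP), which reached 133 CPM ± 3.97 from 15.0 CPM ± 1.14, the amino acid transporter SLC3A2 (2.66 ± 0.11) and DDIT4, an inhibitor of mTORC1 (3.04 ± 0.15). All 14 endoplasmic reticulum (ER) chaperone and unfolded protein response genes rose, with XBP1 at 1.65 ± 0.08 and the disulfide isomerase PDIA4 at 2.59 ± 0.18. Of 19 p53 targets 13 rose, including the stress cytokine GDF15 (5.85 ± 0.29), the cell cycle inhibitor CDKN1A (4.46 ± 0.24) and the pro-apoptotic genes BBC3 (2.59 ± 0.14) and PMAIP1 (3.67 ± 0.21), and 4 fell. Immediate-early genes, the fast transcriptional responders, had 10 of 11 rising, with FOSB at 5.32 ± 0.36 and KLF4 at 5.64 ± 0.61. These lists stood above other genes by camera, with adjusted p of 9.55e-25, 4.76e-23, 4.8e-12, 1.66e-09 and 2.11e-07. With an estimated correlation, each of the 5 kept its call (adjusted p = 5.99e-06, 5.99e-06, 0.028, 0.00919 and 0.0407). Adjusted over the list alone, the same numbers of members rose in all 5.

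Among autophagy and lysosome genes 11 of 19 rose and 6 fell, led by the cargo receptor SQSTM1 (2.88 ± 0.11) and GABARAPL1 (2.35 ± 0.15), and camera gave an adjusted p of 0.00134 (0.0191 with an estimated correlation). Proteasome subunits had 17 of 24 rising, such as PSMD11 (1.34 ± 0.11), and adjusted over the list alone 19 rose (camera adjusted p = 4.69e-05, but adjusted p = 0.0757 with an estimated correlation). Heat shock proteins had 8 of 12 rising (9 adjusted over the list alone), with HSP90AB1 at 2.20 ± 0.17 and the co-chaperone BAG3 at 1.76 ± 0.15, while HSPA4L fell by 1.13. Their camera adjusted p was 0.00296, against an adjusted p of 0.291 with an estimated correlation. Hypoxia and glycolysis genes gave 11 of 19 rising (12 adjusted over the list alone), with the angiogenic factor VEGFA at 1.45 ± 0.08, and 4 falling, among them lactate dehydrogenase LDHA at -1.30 (camera adjusted p = 0.00267, adjusted p = 0.134 with an estimated correlation). Cholesterol synthesis genes fell in 13 of 19 cases, with DHCR7 at -1.12 ± 0.10 and HMGCS1 at -1.33 ± 0.16, while INSIG1, which restrains the same pathway, rose by 2.02 (camera adjusted p = 0.00836, adjusted p = 0.134 with an estimated correlation). Cytosolic ribosomal protein genes rose in 17 of 24 cases, RPLP1 by 1.49 ± 0.11 (camera adjusted p = 1.6e-06, adjusted p = 0.172 with an estimated correlation). The C/EBP family had 1 of 4 members rising, CEBPB (camera adjusted p = 0.00134, and 0.0155 with an estimated correlation), and aryl hydrocarbon receptor targets 4 of 5 (0.000786, and 0.012 with an estimated correlation). All 13 mitochondrially encoded mRNAs fell, including MT-ND5 (-1.39 ± 0.16) and MT-CO3 (-1.24 ± 0.18), and camera gave 3.07e-05 (adjusted p = 0.291 with an estimated correlation).

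Neuronal wiring genes fell in wild-type cells after 6-OHDA. Among axon guidance and outgrowth genes 13 of 19 fell and 3 rose, with the semaphorin receptor subunit PLXNA4 at -4.13 ± 0.28, the netrin receptor UNC5D at -4.16 ± 0.23 and the Slit receptor ROBO1 at -1.46 ± 0.10 (camera adjusted p = 1.12e-06, and 0.012 with an estimated correlation). Of 21 pan-neuronal and synaptic genes 13 fell, including the microtubule proteins MAP2 (-1.98 ± 0.10) and DCX (-2.03 ± 0.13), while 4 rose, such as the heavy neurofilament NEFH (1.58 ± 0.09). Their camera adjusted p was 0.000226, with an adjusted p of 0.134 with an estimated correlation. Dopaminergic genes went both ways: the GDNF receptor RET fell by 1.57, while GCH1, which makes the cofactor of tyrosine hydroxylase, rose by 3.11 ± 0.44 and the transcription factor NR4A2 by 1.61 ± 0.17. Other large changes included the opioid precursor PENK (-4.88 ± 0.32), the adhesion molecule NCAM2 (-5.42 ± 0.37), the thyroid hormone deiodinase DIO3 (6.52 ± 0.66) and the transferrin receptor TFRC (2.35 ± 0.25). CDKN1B had 0 counts in all 4 untreated wild-type libraries and 8.50 CPM ± 1.65 after treatment, at least 74.3-fold higher than the floor of 3 counts over the group. In alpha-synuclein cells, CDKN1B stood at 2.43 CPM ± 2.31 untreated and 1.95 CPM ± 1.41 treated, so its mean did not rise in that genotype.

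In all, edgeR called 8634 genes in wild-type cells, 4277 higher and 4357 lower, of which 3364 changed at least 2-fold. The treated wild-type libraries had a mean of 0.676% of counts in mitochondrial mRNAs against 0.949% in untreated ones, and 3 of the 4 were the shallowest of their lane.

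**Figure D2:**
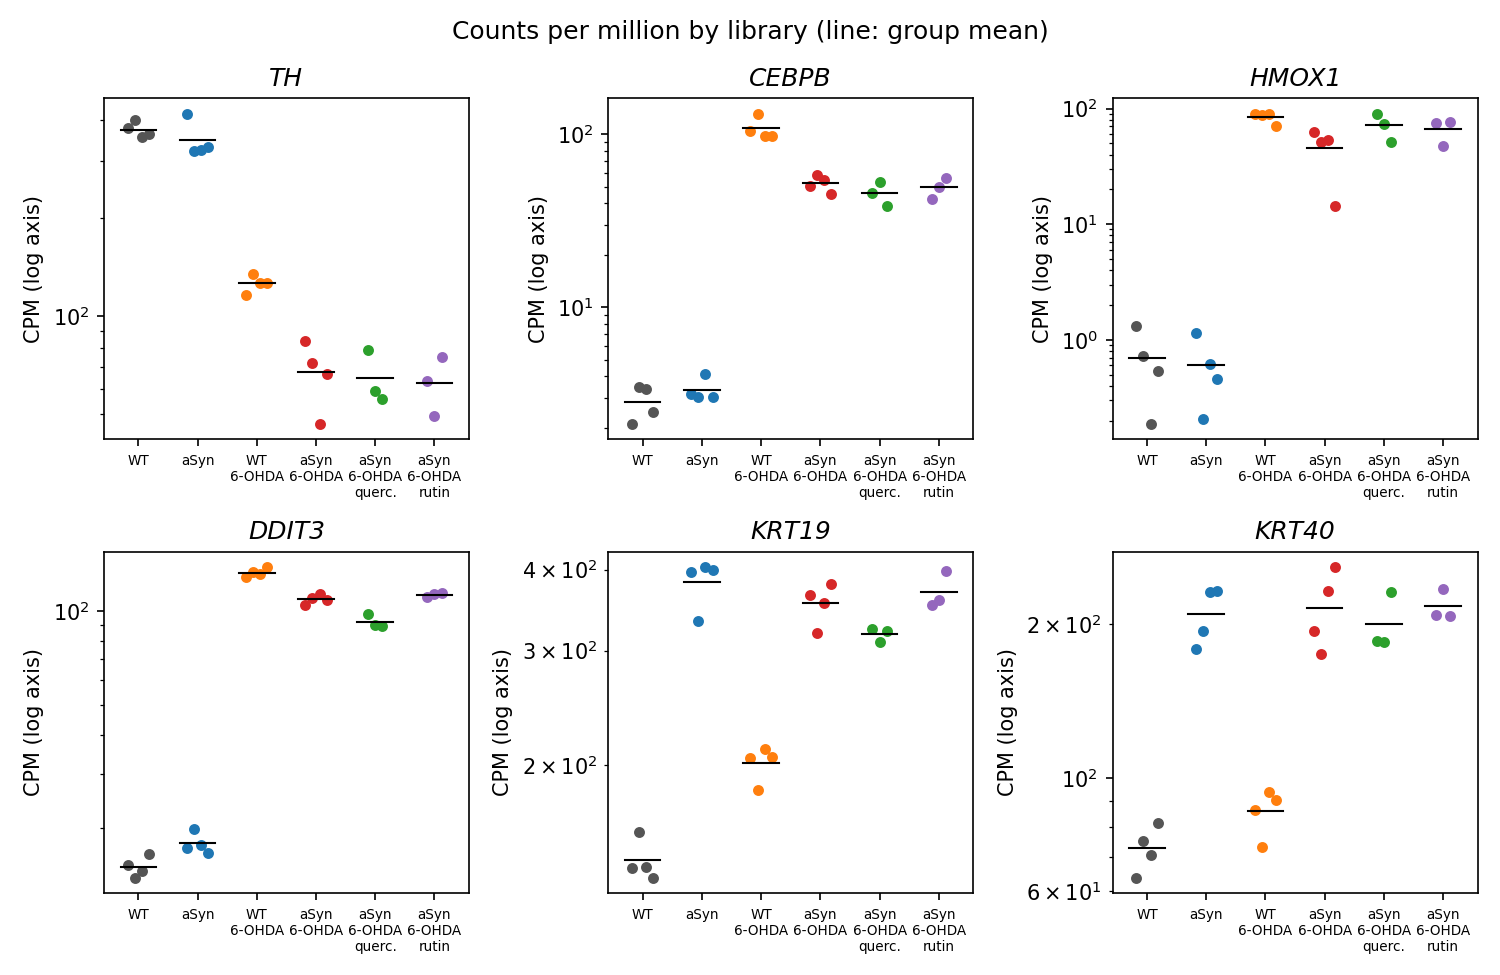
CPM (log axis) of TH, CEBPB, HMOX1, DDIT3, KRT19 and KRT40 in each library (points) of the 6 groups, with a line at each group mean. CEBPB stood at means of 2.86 and 3.33 CPM in untreated wild-type and alpha-synuclein cells and 108 and 52.1 CPM after 6-OHDA.

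In alpha-synuclein cells 6-OHDA was tested against untreated cells of the same genotype. CEBPB rose from 3.33 CPM ± 0.536 to 52.1 CPM ± 5.76, a log2 change of 3.93 ± 0.16 (adjusted p = 1.47e-13). TH fell from 348 CPM ± 47.1 to 67.3 CPM ± 15.5, a change of -2.37 ± 0.15 (adjusted p = 7.34e-11). HMOX1 rose by 6.33 ± 0.47, and the cystine transporter gene SLC7A11 by 4.69 ± 0.22. AKR1C3 stood at 0.903 CPM ± 0.289 and 1.24 CPM ± 0.449 (0.40 ± 0.43, adjusted p = 0.472).

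In alpha-synuclein cells NRF2 targets rose with 6-OHDA in 16 of 18 cases and 1 fell, with NQO1 at 4.01 ± 0.17, GCLM at 3.10 ± 0.14 and the thioredoxin reductase TXNRD1 at 1.65 ± 0.07 (camera adjusted p = 2.82e-29). ATF4 targets rose in 17 of 19 cases, DDIT3 by 2.61 ± 0.07 and the secreted glycoprotein STC2 by 2.97 ± 0.21 (2.49e-23). ER chaperone genes rose in 13 of 14 cases, including HERPUD1, a component of ER-associated degradation, at 2.00 ± 0.11 (2.89e-11). With p53 targets (13 of 19 higher, 7.16e-09), these lists held with an estimated correlation, at adjusted p = 4.21e-07, 4.69e-07, 0.0392 and 0.00784. GDF15 rose by 4.46 ± 0.23, CDKN1A by 3.49 ± 0.22 and PMAIP1 by 2.77 ± 0.18. Adjusted over the list alone, the same numbers rose in these 4 lists.

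Proteasome subunits rose in 19 of 24 cases, with PSMD14 at 2.09 ± 0.23 and PSMB4 at 1.38 ± 0.13 (camera adjusted p = 5.61e-09, and 0.0136 with an estimated correlation). Autophagy genes rose in 9 of 19 cases, SQSTM1 by 2.11 ± 0.10 (0.00126, and 0.0181 with an estimated correlation). Heat shock proteins rose in 10 of 12 cases, HSP90AB1 by 1.96 ± 0.17 (camera adjusted p = 0.000391, adjusted p = 0.214 with an estimated correlation). Immediate-early genes rose in 8 of 11 cases, among them FOS (4.51 ± 0.34) and FOSB (4.54 ± 0.32), and 2 fell (camera adjusted p = 0.000148, adjusted p = 0.16 with an estimated correlation). Hypoxia genes rose in 11 of 19 cases, with the oxygen-sensing hydroxylase EGLN3 at 3.26 ± 0.24, and 5 fell, while cholesterol synthesis genes fell in 10 of 19 cases, with lanosterol synthase LSS at -1.01 ± 0.10. Both lists had a camera adjusted p of 0.0126, and an adjusted p of 0.16 with an estimated correlation. Adjusted over the list alone, these counts were the same. The C/EBP family had 2 of 4 members rising, CEBPB and CEBPG (1.93 ± 0.35), with a camera adjusted p of 0.000391 (0.00784 with an estimated correlation). Of aryl hydrocarbon receptor targets 2 of 5 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.0126, and 0.0392 with an estimated correlation).

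Axon guidance genes fell in 12 of 19 cases (13 adjusted over the list alone), with PLXNA4 at -3.74 ± 0.28, UNC5D at -2.61 ± 0.20 and the netrin receptor DCC at -2.30 ± 0.19 (camera adjusted p = 6.04e-06, and 0.00784 with an estimated correlation). Synaptic and pan-neuronal genes fell in 13 of 21 cases, including the adhesion molecule NCAM1 (-1.57 ± 0.15), and 3 rose (camera adjusted p = 4.33e-05, adjusted p = 0.0851 with an estimated correlation). RET stood at -2.16, PENK at -4.95 and the T-box factor EOMES at -4.84, all called lower, whereas FAM114A1 rose by 6.27 ± 0.46. EdgeR called 7820 genes, 3799 higher and 4021 lower, and 2376 changed at least 2-fold. The lane differed between these groups in every library, so its effect cannot be told apart from that of 6-OHDA here.

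Both genotypes shared much of their 6-OHDA response. Across the 16601 tested genes, the log2 changes correlated at r = 0.669 (jackknife SE 0.0786 over the 16 libraries, with r of 0.624 to 0.693 when each was left out), although genes are not independent replicates. Higher in both genotypes were 2315 genes, where independent lists of these sizes would share 979, and lower in both were 2640, against 1055. Opposite calls numbered 272, against 2033. No library was shared between these comparisons. Without the low-count filter, r was 0.377 over 29867 genes.

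**Figure D3:**
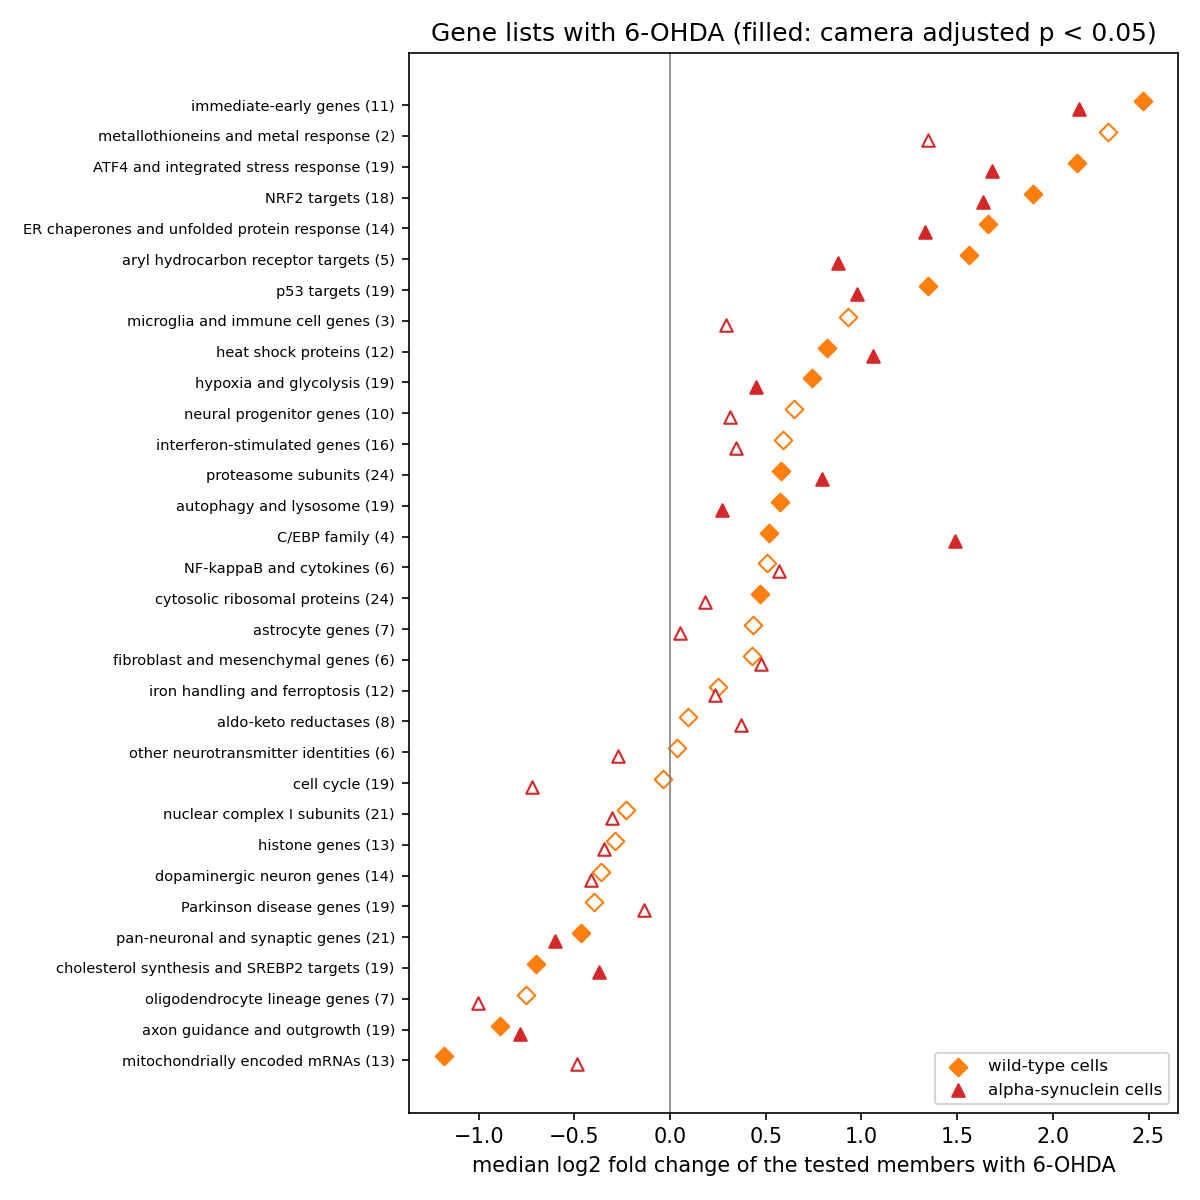
Median log2 fold change (horizontal axis) of each gene list after 6-OHDA in wild-type and in alpha-synuclein cells, 1 point per list and genotype, filled where camera called the list. Among NRF2 targets the medians were 1.90 and 1.63, and among axon guidance genes -0.89 and -0.78.

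Alpha-synuclein overexpression was examined next in untreated cells, within lane 1. CEBPB (0.26 ± 0.21, adjusted p = 0.797), TH (-0.10 ± 0.14, adjusted p = 0.89) and AKR1C3 (0.33 ± 0.46, adjusted p = 0.9) did not pass the threshold. Keratin genes of chromosome 17 were among the genes that were higher. KRT19, a type I keratin of simple epithelia, stood at 142 CPM ± 10.4 in wild-type and 383 CPM ± 33.3 in alpha-synuclein cells (1.43 ± 0.08, adjusted p = 7.74e-11).

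KRT40 was higher by 1.52 ± 0.12 and KRT33B by 1.43 ± 0.16, both hair-type keratins. Higher as well were the muscle gene KLHL40 (1.22 ± 0.23), the orphan receptor GPR142 (1.19 ± 0.19), the adhesion receptor ADGRB1 (0.95 ± 0.14) and the prostaglandin D synthase PTGDS (0.85 ± 0.18). Among called genes that were lower, SEMA3D, a secreted semaphorin, fell by 1.38 (SE 0.15, adjusted p = 2.39e-05), PLXNA4 by 1.12, the netrin receptor UNC5C by 1.29, the protocadherin PCDH10 by 1.30 and DAB1, the reelin adaptor, by 1.60. Also lower were SYNPR (-1.41 ± 0.23), the AMPA receptor regulator SHISA6 (-1.40 ± 0.22), the sodium-calcium exchanger SLC8A1 (-1.43 ± 0.20), SUSD4 (-1.43 ± 0.27) and SPTSSB, a subunit of serine palmitoyltransferase (-1.44 ± 0.30). The urea cycle enzyme ASS1 fell by 1.17 and the microtubule protein MAPT by 0.64.

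Of 19 axon guidance genes 2 were lower and 0 higher (5 lower adjusted over the list alone), with a camera adjusted p of 0.00367 (adjusted p = 0.34 with an estimated correlation). Pan-neuronal and synaptic genes had 0 of 21 called (1 higher and 3 lower adjusted over the list alone), with a median of 0.000558, a mean of -0.02 and a camera adjusted p of 0.811. Mitochondrially encoded mRNAs had 0 of 13 called by edgeR, over all genes or adjusted over the list alone, but camera placed them higher (adjusted p = 0.00458, adjusted p = 0.937 with an estimated correlation). In all 108 genes were called, 62 higher and 46 lower, with 32 at least 2-fold. Leaving out the 2 alpha-synuclein libraries with several barcode numbers left 11 calls, and of the genes named here KRT40, KRT33B, KRT19 and SEMA3D kept theirs. KLHL40, PTGDS, DAB1, SPTSSB, SUSD4, UNC5C, ASS1, PLXNA4 and MAPT also lost their calls without alpha-synuclein replicate 4, and PTGDS, DAB1, SPTSSB, UNC5C and MAPT without several other single libraries of these groups. Without alpha-synuclein replicate 4 or replicate 2 the counts were 33 and 239, without wild-type replicates 1, 3 and 4 they were 61, 47 and 66, and without treated alpha-synuclein replicate 4 the count was 197.

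In 6-OHDA-treated cells, alpha-synuclein and wild-type libraries were compared across lanes. CEBPB was lower in alpha-synuclein cells, at 52.1 CPM ± 5.76 against 108 CPM ± 16.1 (-1.07 ± 0.13, adjusted p = 2.16e-05), and TH was lower, at 67.3 CPM ± 15.5 against 126 CPM ± 7.72 (-0.90, adjusted p = 0.000209). The neurotrophin receptor NGFR was lower by 3.30 (SE 0.37), and the kinase ROCK1 was higher by 3.24 ± 0.41. AKR1C3 changed by 0.61 ± 0.54 (adjusted p = 0.445). Keratins KRT19 (0.82 ± 0.08), KRT40 (1.33 ± 0.13) and KRT33B (0.99 ± 0.17) were higher.

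All 13 mitochondrially encoded mRNAs were higher in treated alpha-synuclein cells, including MT-ND4L (2.24 ± 0.30), MT-ND3 (1.71 ± 0.27), MT-ND1 (1.26 ± 0.22) and MT-ND5 (1.12 ± 0.16), all subunits of respiratory complex I. Camera gave 1.26e-10, against an adjusted p of 0.315 with an estimated correlation. Of 24 cytosolic ribosomal protein genes 15 were lower and 0 higher, such as RPL13 (-0.86 ± 0.10), RPL3 (-0.89 ± 0.13), RPL18 (-0.81 ± 0.12) and RPS19 (-0.70 ± 0.10), with camera at 2.57e-08 (adjusted p = 0.315 with an estimated correlation). Immediate-early genes were lower in 3 of 11 cases, IER2 (-1.37 ± 0.16), JUN (-0.59 ± 0.10) and MYC (-0.78 ± 0.18), with camera at 0.000617. ATF4 targets were lower in 8 of 19 cases, with DDIT3 at -0.28 ± 0.07, DDIT4 at -0.66 ± 0.13 and ATF5 at -0.84 ± 0.19, and higher in 2, with camera at 0.0422. Both had an adjusted p of 0.315 with an estimated correlation. Parkinson disease genes gave 5 of 19 higher and 3 lower, with the lipid transfer protein VPS13C at 0.89 ± 0.13 and GIGYF2 at 0.42 ± 0.07 (camera adjusted p = 0.05 after rounding, adjusted p = 0.815 with an estimated correlation). Adjusted over the list alone, the count of higher Parkinson disease genes was 6 and all other counts in these lists were the same.

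Camera called neither the pan-neuronal nor the dopaminergic list in this comparison. Of the neuronal genes named here, NEFM (-0.38 ± 0.07), NEFH (-0.47 ± 0.09), ELAVL3 (-0.67 ± 0.08), RET (-0.90 ± 0.22) and NR4A2 (-0.61 ± 0.16) were lower and MAP2 (0.46 ± 0.10) was higher. The p53 targets BBC3 (-0.98 ± 0.13) and BTG2 (-0.88 ± 0.14) were lower. Among redox genes, SLC7A11 (0.88 ± 0.19), TXNRD1 (0.39 ± 0.07) and the lipid-handling ACSL4 (0.83 ± 0.14) were higher, and SRXN1 (-0.45 ± 0.10) and the lipid peroxide reductase GPX4 (-0.59 ± 0.10) lower. EdgeR called 4537 genes, 2395 higher and 2142 lower, and 483 differed at least 2-fold. Across genes these changes followed GC content (r = -0.544), and after each library's GC and length trend was removed 1816 genes were called, 1433 of them among the 4537. With that correction the calls of TH (-0.40, adjusted p = 0.0603, over all alternatives 3.61e-07 to 0.0603), DDIT4, ATF5, SLC3A2, NEFH, MAP2, SLC7A11 and GPX4 were lost. Mitochondrial mRNAs were then higher in 11 cases, ribosomal protein genes lower in 11 and higher in 1, and the ATF4 list had a camera adjusted p of 0.145.

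The combined model, treated alpha-synuclein cells against untreated wild-type cells, joined both changes and again differed in lane. CEBPB rose by 4.20 ± 0.18 while TH fell by 2.47 (SE 0.15), with adjusted p of 3.13e-13 and 2.82e-11. AKR1C3 changed by 0.73 ± 0.49 (adjusted p = 0.239). The largest increases included HMOX1 (5.97 ± 0.51), GDF15 (5.34 ± 0.29), SLC7A11 (4.95 ± 0.24), FOSB (4.70 ± 0.37), ATF3 (4.47 ± 0.38), the netrin receptor UNC5B (4.26 ± 0.23) and KLF4 (4.75 ± 0.64). The largest decreases included EOMES (-5.56 ± 0.35), PENK (-5.51 ± 0.32), PLXNA4 (-4.86 ± 0.28), SUSD4 (-4.41 ± 0.37), SEMA3D (-3.82 ± 0.19) and SEZ6L (-3.83 ± 0.43).

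NRF2 targets rose in 16 of 18 cases in the combined model, of ATF4 targets 17 of 19, of ER chaperones 14 of 14, of p53 targets 14 of 19 and of proteasome subunits 19 of 24 (20 adjusted over the list alone). Examples were NQO1 (3.94 ± 0.17), TXNRD1 (1.63 ± 0.07), DDIT3 (2.85 ± 0.08), STC2 (3.04 ± 0.22), HERPUD1 (2.07 ± 0.11), CDKN1A (4.04 ± 0.23) and PSMD14 (2.14 ± 0.25). Camera adjusted p ranged from 1.03e-27 for NRF2 targets to 5.09e-09 for the proteasome, and all 5 held with an estimated correlation, at 7.82e-07 and 0.0138 for those lists. Axon guidance genes fell in 13 of 19 cases, with DCC at -2.50 ± 0.19 (2.74e-08, and 0.00142 with an estimated correlation). Pan-neuronal genes fell in 13 of 21 cases, among them MAP2 (-1.52 ± 0.10) and the neurofilaments NEFL (-1.04 ± 0.09) and NEFM (-0.88 ± 0.07), although NEFH rose by 1.12 ± 0.09 (camera adjusted p = 1.64e-05, adjusted p = 0.0643 with an estimated correlation). RET fell by 2.47, and the SREBP2 target DHCR7 by 1.24. Camera called 15 of the 32 lists here. Those not yet given were heat shock proteins (10 of 12 higher and 1 lower, adjusted p = 0.000112), autophagy genes (11 and 3 of 19, 0.000291), immediate-early genes (8 and 2 of 11, 0.000296), the C/EBP family (2 and 0 of 4, 0.00115), aryl hydrocarbon receptor targets (3 and 0 of 5, 0.00192) and hypoxia genes (12 and 5 of 19, 0.00833), all placed higher, and cholesterol synthesis genes (9 of 19 lower and 1 higher, 10 lower adjusted over the list alone, 0.00361) and oligodendrocyte lineage genes (4 of 7 lower, 0.0351), placed lower. With an estimated correlation autophagy genes, the C/EBP family and aryl hydrocarbon receptor targets kept their calls (adjusted p = 0.00818, 0.0129 and 0.0138), and the other 5 had an adjusted p of 0.0731 to 0.152. The combined model had 7448 calls, 3613 higher and 3835 lower, and 2370 of at least 2-fold.

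The interaction asked whether 6-OHDA acted differently in the 2 genotypes. CEBPB rose less in alpha-synuclein than in wild-type cells (-1.34 ± 0.25, adjusted p = 0.0011), and TH fell further (-0.80 ± 0.20, adjusted p = 0.00729). AKR1C3 (0.28 ± 0.71, adjusted p = 0.841) showed no difference past the threshold.

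Immediate-early genes differed in 3 of 11 cases, all lower (4 adjusted over the list alone), among them IER2 at -1.52 ± 0.22 and JUN at -0.73 ± 0.14. Their camera adjusted p was 0.0197, and 0.109 without treated alpha-synuclein replicate 4. Camera did not call p53 targets (6 of 19 lower and 2 higher, adjusted p = 0.233), of which BTG2 stood at -1.42 ± 0.19 and BBC3 at -1.18 ± 0.19. It did not call ATF4 targets either (6 of 19 lower and 1 higher, adjusted p = 0.087, and 0.0122 without treated alpha-synuclein replicate 4), of which ATF3 stood at -1.99 ± 0.52 and DDIT3 at -0.52 ± 0.10. The counts of both were the same adjusted over the list alone. Ribosomal protein genes were lower in 10 of 24 cases (13 adjusted over the list alone), RPL3 by 1.30 (SE 0.18) and RPL13 by 0.83 (SE 0.15), with camera at 2.23e-05. Mitochondrially encoded mRNAs were higher in 4 of 13 cases (7 adjusted over the list alone), with MT-ND4L at 1.97 ± 0.39 and MT-ND3 at 1.45 ± 0.36, with camera at 0.000433. The 3 called lists had an adjusted p = 0.816 with an estimated correlation. Large single-gene differences included ROCK1 (3.55 ± 0.51), the N-terminal acetyltransferase NAA30 (2.68 ± 0.53), the ER chaperone CLGN (3.87 ± 0.86), ceramide kinase CERK (-4.19 ± 0.92), the cyclin CCNI (-3.37 ± 0.66) and NGFR (-2.76 ± 0.50). UNC5D (1.55 ± 0.30), MAP2 (0.74 ± 0.13) and DCX (0.81 ± 0.18) fell less in alpha-synuclein cells, while NEFH rose less (-0.76 ± 0.13) and ELAVL3 differed by -0.89 ± 0.12. Metabolic genes with a difference were PFKFB3, a regulator of glycolysis (-0.81 ± 0.11), the cholesterol enzyme SQLE (1.84 ± 0.35), VEGFA (-0.47 ± 0.11), ACSL4 (1.18 ± 0.19), GPX4 (-0.77 ± 0.14) and the metal transporter SLC39A14 (-0.93 ± 0.19).

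EdgeR called 3594 interactions, 1854 higher and 1740 lower, 711 of them at least 2-fold. These effects followed GC content across genes (r = -0.560), and with the trend removed 734 genes were called, 595 of them shared. The calls of CEBPB (-0.69, adjusted p = 0.0766, over all alternatives 5.2e-05 to 0.0766), TH (-0.14, adjusted p = 0.754, over all alternatives 0.00174 to 0.754), BBC3, MT-ND3, DCX, SQSTM1, VEGFA and GPX4 were then lost, ribosomal protein genes were lower in 6 cases and mitochondrial mRNAs higher in 1. Without the alpha-synuclein libraries with several barcode numbers, 1978 genes were called and ATF3 was not, and after thinning to the shallowest total DDIT3 was not.

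Quercetin was compared with no compound in 6-OHDA-treated alpha-synuclein cells, within lane 2. No change past the threshold was found in CEBPB (-0.17, 95% interval -0.46 to 0.12), TH (-0.07, -0.40 to 0.26) or AKR1C3 (0.56, -0.35 to 1.47), with adjusted p from 0.574 to 0.89. ER chaperone genes were the clearest group: 8 of 14 fell (12 adjusted over the list alone), among them HSP90B1, the ER form of HSP90 (-1.10 ± 0.25), the disulfide isomerase PDIA6 (-0.89 ± 0.20), DNAJB11 (-0.79 ± 0.18) and HERPUD1 (-0.57 ± 0.12, adjusted p = 0.0158). Camera gave 8.95e-10, against an adjusted p of 0.218 with an estimated correlation. Without treated alpha-synuclein replicate 4, 2 of the 14 fell and camera gave 4.07e-10. NGFR rose by 2.12 ± 0.38 (adjusted p = 0.0107), and SNCG, which encodes gamma-synuclein, fell by 0.90 (SE 0.13, adjusted p = 0.00398).

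Other lists had few members called with quercetin. Of 19 ATF4 targets 1 was lower, the mitochondrial PEP carboxykinase PCK2 at -0.91 ± 0.19 (1 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.286), and the cystine transporter gene SLC7A11 stood at -0.94 ± 0.20. Of 19 axon guidance genes 2 were lower, the ephrin receptor EPHA5 (-0.80 ± 0.18) and ROBO2 (-0.59 ± 0.15), with 1 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.484). Of 21 pan-neuronal and synaptic genes 2 were lower, among them the synaptic vesicle protein SYP (-0.37 ± 0.09), and 1 was higher, NEFH (0.46 ± 0.10), with 7 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.161). The vesicular glutamate transporter SLC17A6 was lower (-0.82 ± 0.21). Of 19 autophagy and lysosome genes 1 was lower, also adjusted over the list alone, cathepsin L (CTSL) at -0.82 ± 0.19 (list median 0.01, mean -0.02, camera adjusted p = 0.915). Of 19 Parkinson disease genes 2 were lower, also adjusted over the list alone, the channel TMEM175 (-0.62 ± 0.15) and VPS13C (-0.53 ± 0.14). Increases included the retinoic acid hydroxylase CYP26B1 (1.24 ± 0.20), the NF-kappaB subunit RELB (1.14 ± 0.22), the transporters SLC6A12 (1.18 ± 0.28) and SLC6A13 (1.24 ± 0.28), CFAP43 (1.31 ± 0.23), SELPLG (1.52 ± 0.38), MGAM (1.72 ± 0.42), BAG3 (0.70 ± 0.16) and IER2 (0.64 ± 0.17). Decreases included SNED1 (-2.01 ± 0.38), PRUNE2 (-2.31 ± 0.56), the protease inhibitor SPINT2 (-1.76 ± 0.43), SLC37A1 (-1.44 ± 0.28), LCNL1 (-1.33 ± 0.22) and CFC1 (-1.20 ± 0.23). HMOX1 stood at 71.7 CPM ± 19.3 (n = 3) against 45.3 CPM ± 21.2 (0.70 ± 0.32, adjusted p = 0.258) and NQO1 changed by 0.05 ± 0.16. The aryl hydrocarbon receptor target TIPARP changed by 0.81 ± 0.24 (adjusted p = 0.0794).

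With quercetin, edgeR called 420 genes, 93 higher and 327 lower, 51 of them at least 2-fold. Camera called 12 of the 32 lists, 10 higher and 2 lower. Besides ER chaperones, it placed immediate-early genes (1 of 11 higher, 4 adjusted over the list alone, adjusted p = 9.93e-06), ribosomal protein genes (0 of 24 called, 2.08e-05), heat shock proteins (1 of 12, 2 adjusted over the list alone, 0.000316), p53 targets (0 of 19, 0.00332) and NRF2 targets (0 of 18 higher, 1 lower, 0.044) higher. Their adjusted p with an estimated correlation ran from 0.218 to 0.316. Without treated alpha-synuclein replicate 4 the camera values were 0.000483, 2.98e-07, 0.0117, 0.0296 and 0.243, in that order. It also placed cell cycle genes (0 of 19 called, adjusted p = 0.0289), NF-kappaB genes (1 of 6 higher, RELB, 0.0289), aryl hydrocarbon receptor targets (1 of 5 higher, 2 adjusted over the list alone, 0.0415), interferon genes (0 of 16, 0.044) and microglia genes (0 of 3, 0.044) higher and Parkinson disease genes (0.0117) lower. Their adjusted p was 0.218 to 0.407 with an estimated correlation, and without replicate 4 camera gave 0.00625, 0.113, 0.033, 0.111, 0.193 and 0.225. The called aryl hydrocarbon receptor target was LRAT, a retinol acyltransferase, at 3.99 CPM ± 0.409 (n = 3) against 0.0587 CPM ± 0.117, which is below the floor of 3 counts in each library without the compound. Its call was lost without treated alpha-synuclein replicate 4 or any of the 3 quercetin replicates, and with the replicate block. The count of called genes moved with the libraries: 26, 98 and 73 without quercetin replicates 2, 1 and 3, and 896, 727 and 84 without treated alpha-synuclein replicates 1, 3 and 4. Of the genes named above, NGFR, CFAP43, LCNL1 and SNCG kept their calls whichever library was left out. RELB, SELPLG, SLC6A12, SLC6A13, MGAM, SPINT2, PRUNE2, SLC37A1, PDIA6, HSP90B1, SLC7A11, PCK2, IER2, EPHA5, SYP, TMEM175, VPS13C, CTSL and SLC17A6 lost theirs without treated alpha-synuclein replicate 4. All of these, and CYP26B1, SNED1, CFC1, HERPUD1, DNAJB11, BAG3, ROBO2 and NEFH, lost theirs without quercetin replicate 2, and many of them without its replicate 1 or 3. A fit of the 2 compared groups alone called 2 genes, and of those named above LCNL1 kept its call there.

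Rutin was tested against the same treated alpha-synuclein libraries. EdgeR called 0 of 16601 genes, with 1790 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0526, while DESeq2 called 285. CEBPB (-0.07, 95% interval -0.37 to 0.22), TH (-0.13, -0.47 to 0.21) and AKR1C3 (0.61, -0.35 to 1.57) had adjusted p of 0.691 to 0.938. The ER chaperone genes that fell with quercetin had smaller values, with HERPUD1 at -0.36 ± 0.12 (adjusted p = 0.248), HSP90B1 at -0.42 ± 0.25 (0.578), PDIA6 at -0.36 ± 0.20 (0.534) and DNAJB11 at -0.31 ± 0.18 (0.557). As these genes were chosen by their quercetin values, smaller values with rutin may follow from that choice. NGFR had a value of 1.56 ± 0.41 (adjusted p = 0.172) and was called without treated alpha-synuclein replicate 1. Further values were LCNL1 -0.70 ± 0.22, SLC7A11 -0.47 ± 0.20, RELB 0.55 ± 0.24, SNED1 -0.47 ± 0.36, HMOX1 0.58 ± 0.32 and SNCG 0.07 ± 0.13.

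Camera placed cytosolic ribosomal protein genes higher with its smallest adjusted p for rutin, 1.97e-14, and 5.03e-17 without treated alpha-synuclein replicate 4. With an estimated correlation the adjusted p was 0.11. Of these 24 genes 0 were called over all genes and 11 were higher adjusted over the list alone. Camera also placed p53 targets (3.39e-05), proteasome subunits (3.39e-05) and heat shock proteins (0.000406) higher and ER chaperones (0.000639) lower, with 0 members called and 2 ER chaperones lower adjusted over the list alone. With an estimated correlation their adjusted p was 0.11, 0.141, 0.286 and 0.314, and without replicate 4 camera gave 0.00248, 0.00305, 0.181 and 0.181. In all camera called 11 of the 32 lists, 8 higher and 3 lower. The remaining 6 were immediate-early genes (0.000639), neural progenitor genes (0.00165), cell cycle genes (0.0442) and NRF2 targets (0.0454), placed higher, and pan-neuronal genes (0.000406) and axon guidance genes (0.00931), placed lower. EdgeR called 0 of their members over all genes, and adjusted over the list alone 1 immediate-early and 1 cell cycle gene were higher and 2 pan-neuronal and 1 axon guidance gene lower. Their adjusted p was 0.11 to 0.447 with an estimated correlation, and without replicate 4 camera gave 0.257, 0.0503, 0.0251, 0.436, 0.0363 and 0.0381. Leaving out treated alpha-synuclein replicate 1 gave 143 calls and leaving out its replicate 3 gave 41. Without untreated alpha-synuclein replicate 2 there were 4, without treated wild-type replicates 2 and 3 there were 3 and 2, and without rutin replicate 2 there were 3.

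Quercetin and rutin, which differ by the sugar that rutin carries, were then compared directly. The labels give neither dose nor time, so whether these matched is not known. SNCG was the single gene called by edgeR, lower with quercetin by 0.97 (SE 0.14, 95% interval -1.26 to -0.68, adjusted p = 0.0101). Unadjusted p was under 0.05 for 1481 genes, and DESeq2 called 77 genes higher and 39 lower. The intervals of the difference were -0.41 to 0.21 for CEBPB, -0.97 to 0.88 for AKR1C3, -0.30 to 0.41 for TH and -0.57 to 0.81 for HMOX1, so differences of these sizes remained possible. HERPUD1 differed by -0.21 (-0.46 to 0.05), PDIA6 by -0.52 (-0.96 to -0.09, adjusted p = 0.448), HSP90B1 by -0.68 (-1.23 to -0.13, adjusted p = 0.427), DNAJB11 by -0.48 (-0.87 to -0.08, adjusted p = 0.444) and SNED1 by -1.53 (-2.36 to -0.71, adjusted p = 0.189). NGFR differed by 0.56 (-0.21 to 1.33), RELB by 0.59 (0.11 to 1.08, adjusted p = 0.440), LCNL1 by -0.64 (-1.11 to -0.16, adjusted p = 0.382) and SLC7A11 by -0.46 (-0.91 to -0.02, adjusted p = 0.543). The genes from HERPUD1 to SLC7A11 were all called with quercetin, and the same quercetin libraries enter here. Their unadjusted intervals may therefore lean away from 0. ER chaperones as a list lay lower with quercetin than with rutin by camera (adjusted p = 0.00119), with 0 of 14 called. So did proteasome subunits (adjusted p = 0.00119, 0 of 24 called, 1 lower adjusted over the list alone) and nuclear complex I subunits (0.0286, 0 of 21 called), while mitochondrial mRNAs lay higher (0.0286, 0 of 13 called). These 4 called lists had an adjusted p of 0.721 with an estimated correlation. The SNCG call was lost without quercetin replicate 1 or 3 or rutin replicate 1, when 0 genes were called, and 58, 8, 5, 4 and 2 genes were called without treated alpha-synuclein replicate 4, untreated alpha-synuclein replicate 2, treated wild-type replicate 2 and treated alpha-synuclein replicates 2 and 1.

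**Figure D4:**
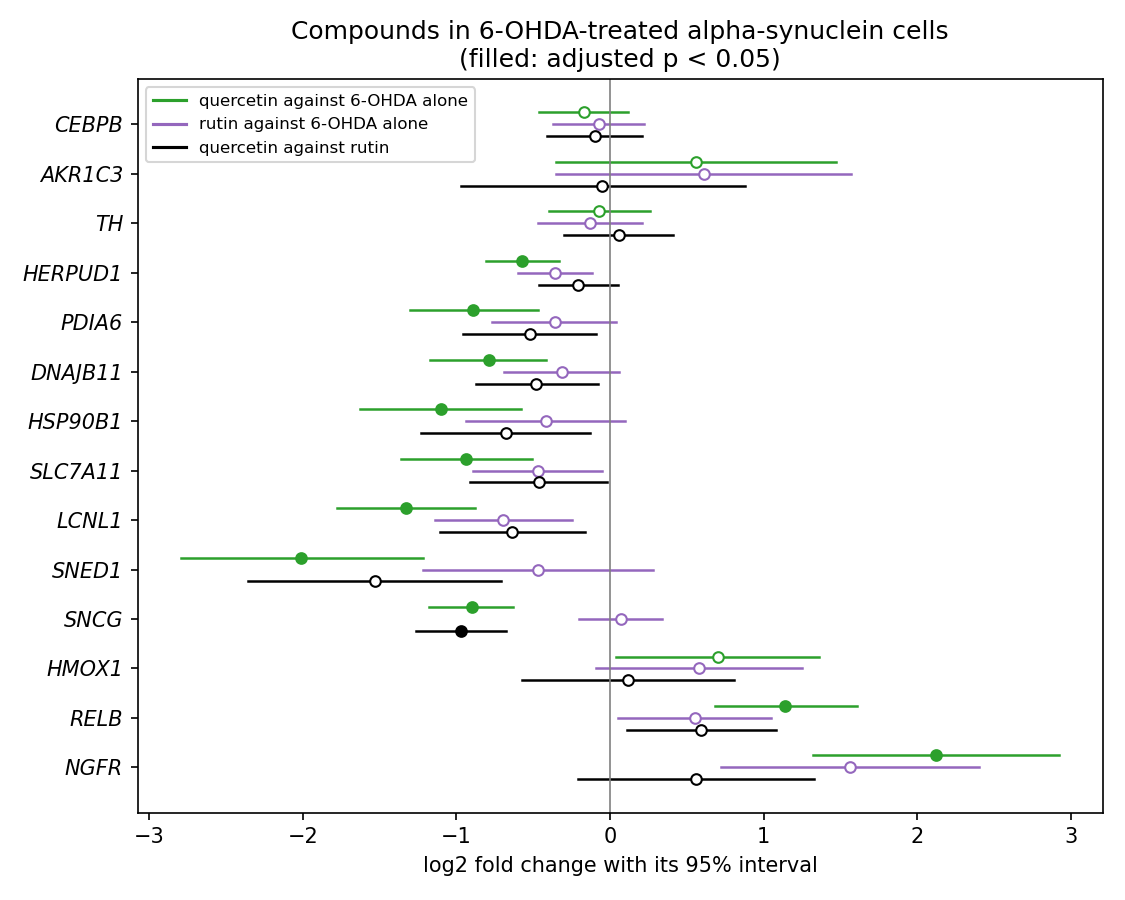
Log2 fold change of named genes with quercetin and with rutin (axis in log2 units), against 6-OHDA-treated alpha-synuclein cells, and of quercetin against rutin, as points with 95% intervals. NGFR stands at 2.12 with quercetin and 1.56 with rutin, and SNCG at -0.90 and 0.07.

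The compounds were applied to test protection, so their changes were set against those of 6-OHDA in alpha-synuclein cells. Of 7820 genes changed by 6-OHDA, 88 were called in the opposite direction with quercetin, where independent lists would give 97.4, and 210 in the same direction, where they would give 100. Across genes r was 0.009, with a covariance of 0.0032. In 20 simulations without effects the shared treated libraries gave a mean r of -0.102 and covariance of -0.0059. When the treated libraries were split 2 and 2, r ranged from -0.034 to 0.293, and without treated alpha-synuclein replicate 4 it was -0.278. Rutin had 0 opposite calls by edgeR, as it had no calls, with r at 0.019 (simulated -0.089, splits -0.001 to 0.300). By DESeq2 25 genes were opposite and 207 in the same direction, where independent lists would give 64.2 and 68.2. The changes with quercetin and with rutin correlated at r = 0.490 with a covariance of 0.0999, where simulation gave 0.093 and 0.0070, and r was 0.008 to 0.106 when each compound had its own 2 control libraries.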

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

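Among the tests below, those of the depth of treated alpha-synuclein replicate 4 and of GC content were set out before their results were seen. The tests of a mixture, of wrong or swapped labels and of other splits were chosen only after the result was seen.

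Of 80 checks for a library far from its group (9 library measures and 11 genes in 4 groups of 4), 12 found one, where chance gives about 1 in 20. In untreated wild-type cells, replicate 4 had a total of 10609641 counts. In untreated alpha-synuclein cells, replicate 1 had fewer genes with a count (20391), a higher pseudogene share (2.14%) and TH at 418.9 CPM, replicate 2 had KRT19 at 333 CPM, replicate 3 had CEBPB at 4.13 CPM and 0.946% of counts in ribosomal protein genes, and replicate 4 had KRT33B at 157 CPM. In treated wild-type cells, replicate 1 had a total of 12642017 counts and replicate 4 had HMOX1 at 70.6 CPM. In treated alpha-synuclein cells, replicate 4 had KRT33B at 139.7 CPM and a first component score of -1.47.

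Treated alpha-synuclein replicate 4 lay between its group, whose other scores were 38.1 to 40.8, and the untreated libraries. A mixture with untreated RNA would need about the same untreated share from genes that rose and genes that fell with 6-OHDA, but the median shares, 0.58 over 136 genes and 0.147 over 150, differed by 0.433. Its greater depth did not account for the gap, which was 43.5 after thinning, against a range of 2.73 over the other 3 libraries. It was not an untreated library with a wrong label, as CEBPB stood at 45.01 CPM against at most 4.13 in untreated alpha-synuclein cells. A weaker or earlier response to 6-OHDA in this sample may remain, as an untested hypothesis.

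The effect of 6-OHDA differed between genotypes by the interaction test in 40 of 59 genes tested for it. These genes were named mostly for large changes or small adjusted p, so a high share follows from their choice, and over all genes 3594 of 16601 differed. Transcription factors, stress genes and TH with negative log2 differences (a weaker rise or a stronger fall in alpha-synuclein cells) were CEBPB (-1.34), TH (-0.80), BTG2 (-1.42), BBC3 (-1.18), IER2 (-1.52), JUN (-0.73), ATF3 (-1.99), DDIT3 (-0.52), SLC3A2 (-0.50), DDIT4 (-0.85), XBP1 (-0.32), PDIA4 (-0.71), GDF15 (-1.39), CDKN1A (-0.97), PMAIP1 (-0.90), BAG3 (-0.68), SQSTM1 (-0.77), PFKFB3 (-0.81) and VEGFA (-0.47). Other negative differences were in RPL3 (-1.30), RPL13 (-0.83), NGFR (-2.76), CERK (-4.19), CCNI (-3.37), NEFH (-0.76), ELAVL3 (-0.89), GPX4 (-0.77), SLC39A14 (-0.93) and NR4A2 (-0.79). Positive differences were in MT-ND4L (1.97), MT-ND3 (1.45), ROCK1 (3.55), NAA30 (2.68), CLGN (3.87), MAP2 (0.74), DCX (0.81), UNC5D (1.55), VPS13C (1.00), SQLE (1.84) and ACSL4 (1.18). The lists that differed were immediate-early genes (camera adjusted p = 0.0197), mitochondrial mRNAs (0.000433) and ribosomal proteins (2.23e-05), each with an adjusted p of 0.816 with an estimated correlation. With GC and length trends removed the interaction had 734 calls against 3594, and those of CEBPB (-0.69), TH (-0.14), BBC3, MT-ND3, DCX, SQSTM1, VEGFA, GPX4, SLC3A2, DDIT4, PDIA4, GDF15, CDKN1A and BAG3 were lost. The calls of NR4A2, SLC3A2, XBP1, PDIA4, GDF15, CDKN1A, PMAIP1 and BAG3 were lost without one or more single libraries. Lane differed between the treated groups, so its effect and that of genotype cannot be told apart here.

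Splits of the same libraries were counted for each comparison. For 6-OHDA, 1 of 35 splits, the real one, called as many genes in wild-type cells (8634, highest other 1) and in alpha-synuclein cells (7820, highest other 2227). The same held in alpha-synuclein against wild-type treated cells (4537, highest other 3) and in the combined model (7448, highest other 2866). That is the smallest share 35 splits can give, and a random grouping was unlikely there. Lane followed the groups in all of these but 6-OHDA in wild-type cells, so the splits cannot tell lane from group. For the interaction 2 of 100 splits did (3594 real, 4387 highest other). The split with 4387 kept the treated groups whole and exchanged untreated wild-type replicate 1 with untreated alpha-synuclein replicate 2. Another that kept them whole called 1330. Most other splits mixed the treated genotypes and so removed their difference. The share therefore cannot tell an interaction from a difference between the treated groups, and chance was not excluded. For alpha-synuclein in untreated cells 2 of 35 splits did (108 real, 592 highest other), so chance was not excluded. For quercetin 2 of 35 did (420 real, 520 highest other, from the split that put treated replicate 1 with the quercetin libraries), so chance was not excluded. For rutin the real split called 0 genes, so all 35 splits reach that number by definition and their share decides nothing (66 highest other). Quercetin against rutin has 10 splits, too few for a share under 0.05, with 1 call in the real split and 0 in the highest other.

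Exchanging replicate 2 of untreated wild-type and alpha-synuclein cells called 592 genes, several times the 108 of the real groups, which points to a structure of these samples. A swap of the labels did not account for it: KRT19 stood at 157.6 CPM in wild-type replicate 2 (134 to 139.4 in the other 3) and 333 CPM in alpha-synuclein replicate 2 (396.6 to 403.3), so each lay toward the other group but far nearer its own. GC content and length bias may account for it: with those trends removed the exchange called 68 genes, 0.673 times the number of the real groups. Of the 108 genes 81 were called again after that correction. No biological explanation was tested for these replicates.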

How the results depend on the processing

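Thinning to the shallowest total, removing GC and length trends and lists without treated alpha-synuclein replicate 4 were chosen after the data were seen. The other alternatives were planned. No named gene reversed direction past the threshold in any alternative, and 227 of 313 gene results were the same under each of at most 31 alternatives. Calls were lost most often in a fit of the compared groups alone (48 of 308 gene results), without the 2 libraries with several barcode numbers (36 of 313) and after thinning (33 of 301). Leaving out 1 library at a time lost 213 calls of 6886 and gained 4. The causes of the changes below were not tested, except that fewer libraries or counts leave less power. The shallowest totals limit genes near 1.49 CPM.

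For alpha-synuclein in untreated cells, 108 calls became 11 without the libraries with several barcode numbers, 63 thinned, 230 by DESeq2, 23 with the compared groups alone, and 33 (without alpha-synuclein replicate 4) to 239 (without its replicate 2) with single libraries left out. Without wild-type replicates 1, 3 and 4 there were 61, 47 and 66, and without treated alpha-synuclein replicate 4 there were 197. With GC trends removed, alpha-synuclein in 6-OHDA cells went from 4537 to 1816 and the interaction from 3594 to 734, and without the libraries with several barcode numbers the interaction had 1978.

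For quercetin, 420 calls became 230 without the libraries with several barcode numbers, 204 thinned, 694 with GC trends removed, 969 by DESeq2, 2 with the compared groups alone, and 26 (without quercetin replicate 2) to 896 (without treated alpha-synuclein replicate 1). Without quercetin replicates 1 and 3 there were 98 and 73, and without treated alpha-synuclein replicates 3 and 4 there were 727 and 84. Genes called against the 6-OHDA change went from 88 to 46 without the libraries with several barcode numbers, 51 thinned, 189 by DESeq2, 0 with the compared groups alone, and to 4 (without quercetin replicate 2) to 157 (without treated alpha-synuclein replicate 1), with 17, 18 and 25 without quercetin replicates 1 and 3 and treated alpha-synuclein replicate 4.

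For rutin, 0 calls by edgeR (1790 unadjusted) became 2 with DESeq2-style size factors, 4 with no filter, 4 thinned, 4 with GC trends removed, 285 by DESeq2, and 0 to 143 (without treated alpha-synuclein replicate 1), with 41 without its replicate 3. Genes called against the 6-OHDA change were 25 by DESeq2 and 0 to 23 with libraries left out, with 23 and 4 without treated alpha-synuclein replicates 1 and 3. Quercetin against rutin had 0 genes higher and 1 lower, and 4 and 4 with no filter, 0 and 0 thinned, 77 and 39 by DESeq2, 12 and 7 with the compared groups alone, and 0 to 30 higher and 0 to 28 lower with libraries left out, the highest without treated alpha-synuclein replicate 4. Without quercetin replicate 1, quercetin replicate 3 or rutin replicate 1 there were 0. Without untreated alpha-synuclein replicate 2 there were 6 and 2, without treated wild-type replicate 2 there were 2 and 3, and without treated alpha-synuclein replicates 2 and 1 there were 1 and 3, and 0 and 2.

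Gene list calls over the 9 comparisons went from 82 to 27 with an estimated correlation and 112 with fry. The correlation of the 6-OHDA responses went from 0.669 to 0.377 with no filter. Replicate numbers did not pair the samples: none of 51 pairs correlated above 0.1 (range -0.138 to 0.0776), and 2 of 22 libraries correlated best with their own number. With the replicate block quercetin had 120 calls and 33 genes against the 6-OHDA change, and no other count of calls moved by over 1.5 times.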

Other observations

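The keratin tests below were chosen after the result was seen, except that of shared reads, which was set out before.

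Camera did not call several further lists with 6-OHDA in wild-type cells. Oligodendrocyte lineage genes fell in 4 of 7 cases there, with the transcription factor OLIG1 at -1.71 ± 0.29 and the myelin enzyme CNP at -1.03 ± 0.10 (camera adjusted p = 0.0919). In alpha-synuclein cells OLIG1 fell by 2.71 and CNP by 1.04, and in the combined model 4 of 7 fell (camera adjusted p = 0.0351, adjusted p = 0.0731 with an estimated correlation). The metallothionein MT1X, which binds zinc and copper, rose by 4.04 ± 0.33 in wild-type and 2.96 ± 0.27 in alpha-synuclein cells, and 1 of 2 metallothioneins tested rose in wild-type cells (0.0878). Neural progenitor genes rose in 6 of 10 cases and fell in 1 (0.0836), Parkinson disease genes fell in 8 of 19 and rose in 1 (0.0604), and nuclear complex I subunits fell in 8 of 21 and rose in 3 (0.482). Counts adjusted over the list alone were the same for all of these.

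The remaining lists with 6-OHDA in wild-type cells were not called by camera. Dopaminergic genes gave 3 higher and 4 lower of 14 (0.627), other neurotransmitter genes 2 and 2 of 6 (0.627), iron genes 5 and 5 of 12 (0.346), interferon genes 6 and 1 of 16 (0.244), histones 2 and 7 of 13 (0.676), aldo-keto reductases 2 and 1 of 8 (0.482), microglia genes 2 and 0 of 3 (0.346) and NF-kappaB genes 1 and 0 of 6 (0.26), the same adjusted over the list alone. Cell cycle genes gave 0 and 5 of 19 (0 and 4 adjusted over the list alone, 0.655), astrocyte genes 2 and 2 of 7 (3 and 2, 0.951) and fibroblast genes 1 and 0 of 6 (0 and 0, 0.406).

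Genes of the type I keratin region of chromosome 17 were higher in alpha-synuclein cells. Between 40958417 and 41528308, 5 genes were called in untreated cells: KRT19 (1.43), KRT33B (1.43), KRT40 (1.52), KRT39 (1.57) and KRTAP2-3 (1.72), with 0.82, 0.99, 1.33, 1.93 and 0.85 in 6-OHDA-treated cells. Chance position was excluded, as 0 of 10000 random sets of 62 genes in a permutation test held as many within 1 Mb. That permutation test gave p = 1e-04, the smallest these draws can give, and the highest random set held 4. Reads shared among the 5 called genes did not account for it, since a median of 0 percent of 31-base words stood in another of them. Words shared with other genes, such as further keratins, were not counted, so reads shared with those were not excluded. Extra copies of the stretch together with its surroundings did not account for it. The other 48 tested genes within 1 Mb had a median of 0.06 (SE 0.0786), and 0 were called by edgeR. Extra copies of the stretch alone were not excluded, as the 3 others inside the region had a median of 0.80. Extra copies of that stretch or of a part of it, an effect of the construct near its site or common regulation may remain as hypotheses.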
